A study of Mus musculus with 33 samples.

How the data were processed

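RNA from mouse thymus was measured on 33 Affymetrix arrays, 1 sample per array. The deposited values are array signal (intensity) on a linear scale, 1 value per probe set. Per the labels they were made with Affymetrix Expression Console 1.0 and MAS5, and the values show that each array was scaled on its own, since the mean signal of an array without its lowest and highest 2% of probe sets was almost equal on all arrays. No normalization between arrays had been applied, and no background settings, scan dates or filters are stated. Poly(A) RNA was primed with oligo-dT. RNA of dissected tissue and RNA of sorted cells were isolated with different kits, so kit and kind of sample cannot be told apart in comparisons of tissue with sorted cells. The control probe sets that give ratios of 3' to 5' signal are not in the deposited table, so these planned ratios were not computed and RNA integrity is unknown.

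The table holds 45037 probe sets, of which 34945 map to 1 gene symbol, 932 to several and 9160 to none. Symbols were looked up by gene number in a RefSeq gene table for 34741 of the probe sets with 1 symbol (0 changed), and 204 were kept as given. An offset of 26.2, the median over arrays of the 25th percentile of the signal, was added before values were put on the log2 scale. Probe sets above the median of their array in at least 3 arrays were kept (30045), and of these the ones with 1 gene symbol were used (24883). Each gene was represented by its probe set with the highest mean, which left 13463 genes, 6423 of them with more than 1 probe set that passed. The other probe sets of a gene were used to check its direction. Listed genes without a probe set that passed were not analysed here.

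All 33 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 7 group means, which left 26 residual degrees of freedom, and with a spread moderated along the mean signal. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its absolute log2 fold change at least 1. The design named 9 comparisons, among them the compartment difference of tissue minus that of sorted thymocytes, an interaction term. Fold changes are group differences of mean log2 values, given with the standard error of the fit. Signals are given on the deposited linear scale as mean ± SD. Adjusted p-values of genes are from limma throughout, and the tests are 2-sided. The fitted fold changes of weak signals are smaller than the ratios of the mean signals, since the offset is added to both groups.

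Gene lists for 29 cell types, pathways and processes of the thymus held 482 genes, of which 419 were tested and 18 stood in more than 1 list. They were tested with camera in limma at a preset correlation of 0.01 and again with a correlation estimated from the arrays. Values of p were adjusted over the lists within a comparison. Counts of called members are given over all genes tested and, where that differed, adjusted over the list alone. In the comparisons described, these counts were otherwise equal. The model, the threshold, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Which lists are described for a comparison was chosen after their results were seen, and the members named from them follow that choice.

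Genes were named by a rule. It takes for each comparison the 6 largest positive and the 6 largest negative log2 fold changes among called genes whose arrays do not overlap between the groups (for the interaction and for the mean of several groups, among called genes). It adds up to 4 called members of each list described, those with the largest absolute change, or the member with the smallest p where none was called, and the markers Cd3e, Thy1, Ptprc, Kit, Aire and Psmb11 in every group. Several genes that the rule takes, from lists or among the largest changes, are covered by the counts alone. Uty, Xist outside the comparison that selects it, and the genes of cholesterol synthesis were added after their values were seen. The sort gate of cortical thymocytes selects on the products of Cd3e, Thy1, Ptprc and Kit, so levels of these genes in sorted cells are no finding. Since it takes cells with no or low CD3, it also selects by maturity. Differences of mature and double-positive thymocyte genes that involve sorted cells may therefore follow in part from the gate.

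Alternatives fixed with the design were an offset of 6.55, quantile normalization, no filter, a stricter filter (above the median in at least 7 arrays and above the 75th percentile in at least 1), the mean of the probe sets of a gene, only probe sets with a plain suffix, a fit of only the groups compared, a block for the replicate number, array weights, and each array left out in turn. A further 3 were chosen after seeing the data, when 13 arrays stood apart by a wide upper tail (a value above 42000 exceeded by 0.1% of the probe sets, a limit also set then): whole cortex 1 to 5, whole medulla 1 to 5 and sorted medullary thymocytes 1 to 3. These are an added term for the wide tail, comparisons within the wide-tail arrays and comparisons within the other arrays. The counts of called genes were compared with those of up to 100 other splits of the same arrays, and an interval for a ratio of medians came from 2000 bootstrap draws. For the shares of medullary signal these were draws of genes, not of arrays.

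The pipeline was tested on simulated data with 200 changed genes. At a log2 fold change of 1, which is the threshold itself, 39% were called in the layout of whole medulla against whole cortex, 45% in that of the sorted thymocytes and 30% in that of perimedullary against subcapsular cortex. At a log2 fold change of 2, 100%, 98% and 96% were called, with 1, 3 and 1 false calls. The number of arrays limits the precision, most of all for the 3 cortical subregions with 3 arrays each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.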

Results

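Gene expression was measured on 33 arrays of RNA from the thymus of C57BL/6J mice, labelled male and 4 to 6 weeks old. Dissected tissue made up 23 of the arrays: whole cortex (n = 7), whole medulla (n = 7), and the subcapsular, central and perimedullary parts of the cortex (n = 3 each). The other 10 arrays held sorted cells: cortical thymocytes (n = 5), gated as CD45 positive with no or low CD3 and with CD90 or CD117, and medullary thymocytes (n = 5). These n hold for every mean ± SD below. The median signal of an array lay between 71.9 and 163 and the value exceeded by 0.1% of its probe sets between 16919 and 75998, and Pearson correlations between arrays of a group lay between 0.937 and 0.988. The number of arrays limits the precision. The titles call the arrays biological replicates, but the labels do not tie dissected regions to animals, so some arrays may share animals. Values of p over regions may then be too small if 1 animal gave several arrays of a group. They may be too large if regions of 1 animal form pairs. Of the 261 tests of a gene list in a comparison, 141 had an adjusted p below 0.05, 103 of these also with an estimated correlation. By comparison these were 17 of 21 for whole medulla against whole cortex, 11 of 12 for medullary against cortical thymocytes, 7 of 14 for the difference between tissue and thymocytes, 7 of 14 for subcapsular against central, 17 of 21 for perimedullary against central, 14 of 17 for perimedullary against subcapsular, 14 of 16 for whole cortex against cortical thymocytes, 16 of 23 for whole medulla against medullary thymocytes, and 0 of 3 for the subregions against whole cortex.

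The comparison of whole medulla with whole cortex asked which transcripts mark the compartments as tissue. Transcripts of medullary epithelium, of genes otherwise restricted to other tissues, of dendritic cells, mesenchyme, antigen presentation and mature thymocytes were higher in the medulla, and those of double-positive thymocytes, cortical epithelium and dividing cells were lower. Aire, the regulator of tissue-restricted gene expression in medullary epithelium, had a signal of 2330 ± 231 in medulla and 25.3 ± 24.2 in cortex. Rag2, part of the recombinase that assembles antigen receptor genes, had 37.4 ± 22.8 in medulla and 5850 ± 617 in cortex. Called genes numbered 2492 higher and 724 lower in medulla.

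**Figure D1:**
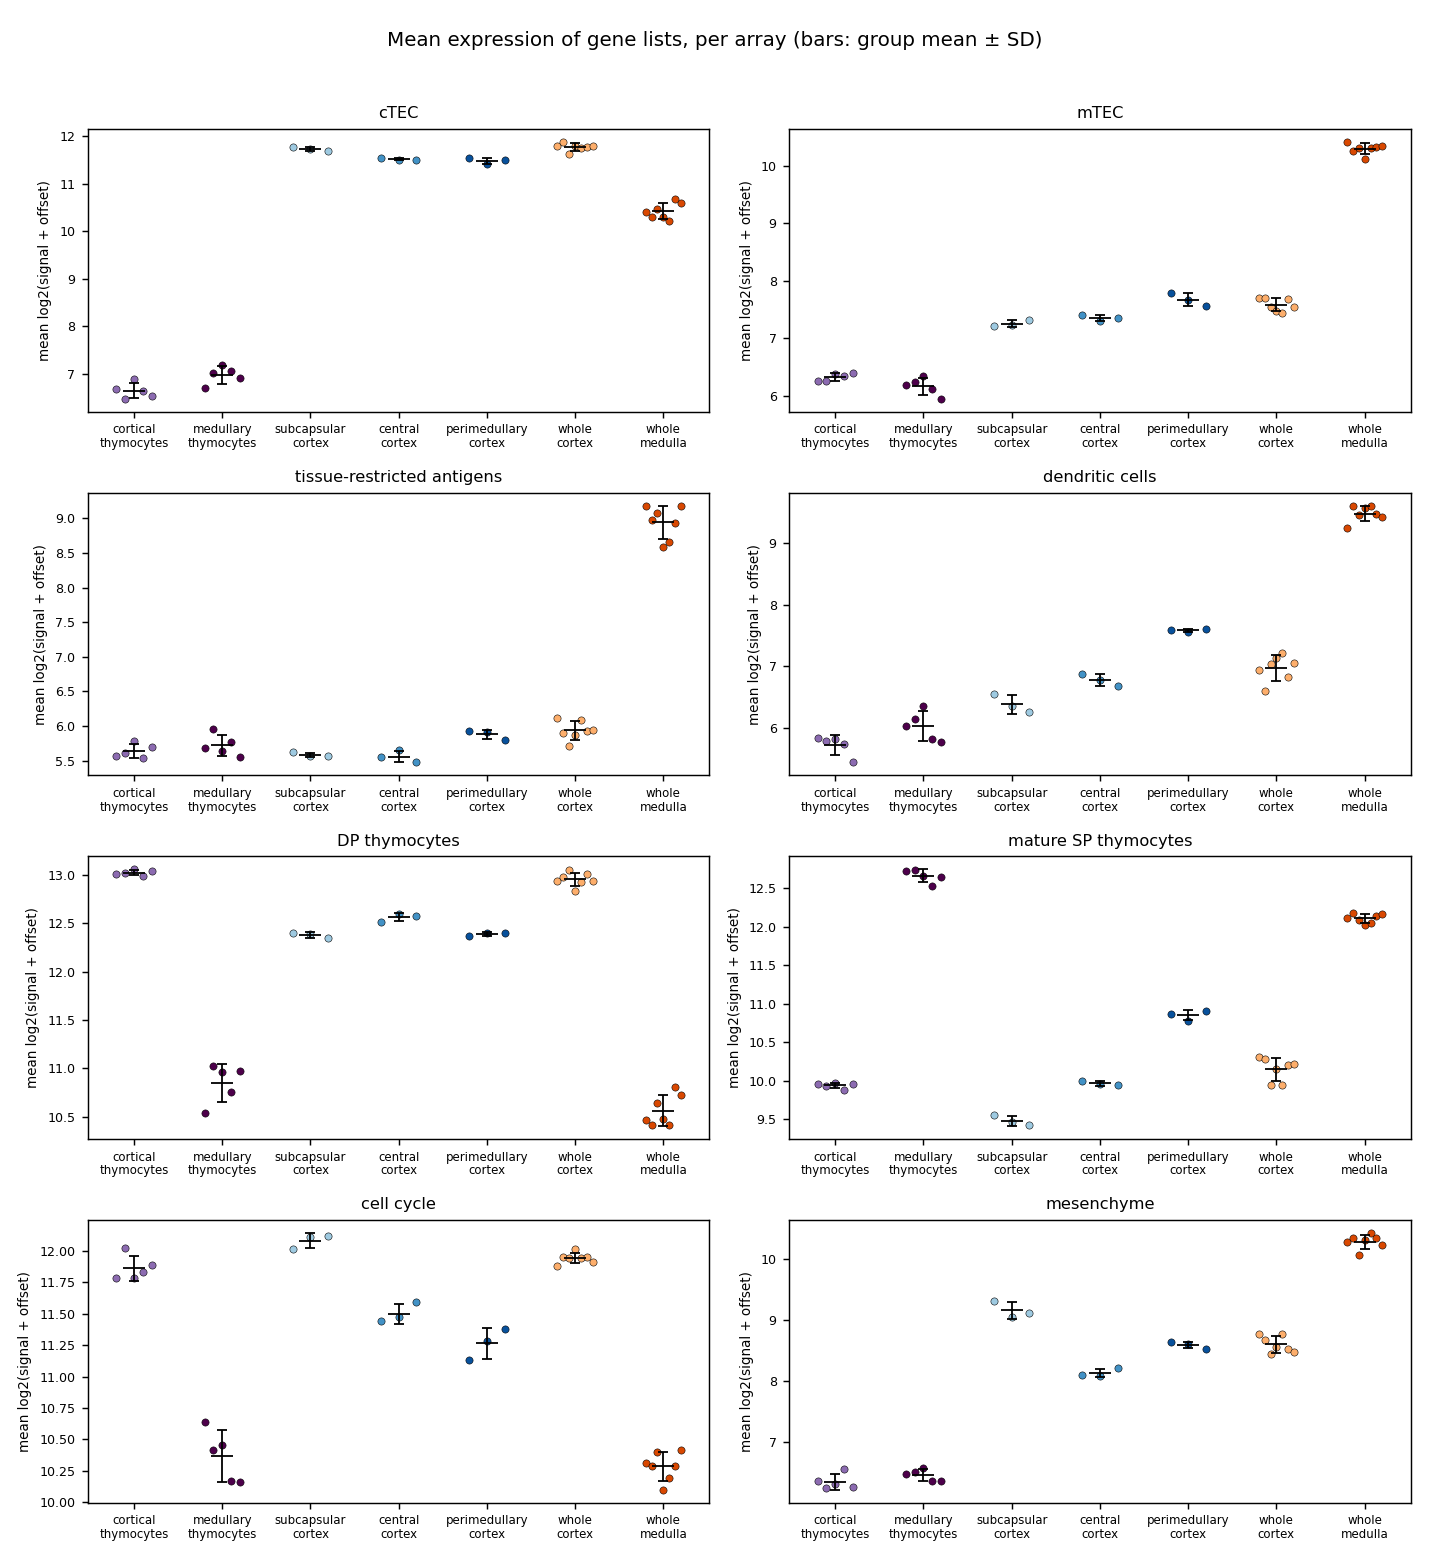
Mean log2(signal + offset) of the tested genes of 8 lists, 1 point per array, in the 7 groups, with bars for the group mean and SD. The lists for medullary epithelium (mTEC) and tissue-restricted antigens are highest in whole medulla, and the lists for double-positive (DP) thymocytes and cell cycle are lowest in whole medulla and sorted medullary thymocytes.

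Of 14 medullary epithelial genes, 12 rose in whole medulla and 2 did not pass the test (median log2 fold change 2.43, camera adjusted p = 1.2e-07). Aire rose by a log2 fold change of 5.63 (SE 0.25, adjusted p = 1.5e-20), Fezf2, a transcription factor for self-antigen expression, by 4.87 (SE 0.2, adjusted p = 3.8e-21), and Krt14, a basal keratin, by 4.52 (SE 0.26, adjusted p = 3.9e-17). Tissue-restricted antigens rose in 19 of 21 cases (median 3.11, camera adjusted p = 4.2e-09). Among them were Reg3g, a gut antimicrobial lectin, at 4830 ± 1300 against 10.2 ± 5.86 (log2 fold change 7.02, SE 0.2), Csn2, the milk protein beta-casein, at 5490 ± 1970 against 46.2 ± 31.7 (6.3, SE 0.26), and Apoa4, an intestinal apolipoprotein, at 1380 ± 379 against 31.3 ± 22.4 (4.64, SE 0.24). Of 14 cortical epithelial genes, 7 fell and 1 rose (median -1.21, camera adjusted p = 7.6e-05). Psmb11, the catalytic subunit of the thymoproteasome, had a log2 fold change of -4.25 (SE 0.18, adjusted p = 4.4e-21), Prss16, the thymus-specific serine protease, had 927 ± 172 in medulla and 14000 ± 1370 in cortex (-3.9, SE 0.13), and Cxcl12, a chemokine, had 899 ± 139 and 7970 ± 395 (-3.13, SE 0.14). The largest rise of all was that of Wfdc18, which encodes a protein with a whey acidic protein domain, at 15800 ± 2370 in medulla and 64.9 ± 38.9 in cortex (log2 fold change 7.55, SE 0.26, adjusted p = 1.9e-23).

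Dendritic cell genes rose in 10 of 12 cases (median 2.11, camera adjusted p = 1.7e-05). Fscn1, an actin-bundling protein of mature dendritic cells, had 22700 ± 6180 in medulla and 486 ± 68 in cortex, and Ccl22, a ligand of CCR4, had 4800 ± 814 and 118 ± 25.4. All 11 tested genes of MHC class II presentation rose (median 2.46, camera adjusted p = 5.7e-08), with H2-Eb1 at 23500 ± 2680 against 2830 ± 494 and Cd74, the invariant chain, at 30600 ± 3560 against 5070 ± 1740. Of 13 MHC class I genes, 6 rose (median 0.936, camera adjusted p = 1e-04), among them Nlrc5, their transactivator, by a log2 fold change of 3.71 (SE 0.1, adjusted p = 2e-26). Chemokine genes rose in 14 and fell in 2 of 18 cases (camera adjusted p = 7.6e-05), with Ccl5 up by 6.05 (SE 0.26) and Cxcl9 up by 5.19 (SE 0.28). Of 14 macrophage genes 5 rose and 2 fell, and the list as a whole did not pass (camera adjusted p = 0.36). Lyz2, a lysozyme, had 16800 ± 2060 in medulla and 2790 ± 512 in cortex, whereas Slc40a1, the iron exporter ferroportin, had 286 ± 36.2 and 1580 ± 340, and Cd163, a scavenger receptor for haemoglobin, had 41.2 ± 32 and 241 ± 65.3. B cell genes rose in 6 and fell in 2 of 10 cases (camera adjusted p = 0.23). Ms4a1, which encodes CD20, had 1420 ± 317 in medulla and 107 ± 30.3 in cortex, and Ighm, the immunoglobulin mu chain, fell by 2.32 (SE 0.11, 6 of its 7 probe sets lower). The brightest Ighm probe set also had 14400 ± 882 in sorted cortical and 5220 ± 917 in sorted medullary thymocytes, where Ms4a1 had 46 ± 15.3 and 61.5 ± 19. The fall of Ighm therefore cannot be read as one of B cells.

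Mesenchymal genes rose in 13 of 19 cases (median 1.22, camera adjusted p = 4.9e-06), such as Tagln, an actin-binding protein of smooth muscle, at 1590 ± 279 against 82.8 ± 43.7 and Mgp, matrix Gla protein, at 4410 ± 679 against 309 ± 135. Endothelial genes rose in 7 of 13 cases (camera adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.06 with an estimated correlation) or the stricter filter, which tests fewer genes. Vwf, von Willebrand factor, had 330 ± 69.1 in medulla and 36.4 ± 24.2 in cortex. Genes of basement membrane and adhesion rose in 11 of 18 cases (camera adjusted p = 7.5e-05), with Cdh1, E-cadherin, at 5390 ± 341 against 566 ± 136. The BMP and TGF-beta list rose in 14 of 19 cases (camera adjusted p = 1.4e-05), with Bmp2 up by 3.21 (SE 0.25) and Smad7, an inhibitor of the pathway, up by 3.16 (SE 0.27). The TNF and NF-kB list rose in 10 of 15 cases (camera adjusted p = 0.00013). Relb, a subunit of the alternative NF-kB pathway, had 2120 ± 179 in medulla and 180 ± 52.6 in cortex. Interferon-response genes rose in 14 of 17 cases (median 2.69, camera adjusted p = 3.6e-12), with Mx1, an antiviral GTPase, up by 3.88 (SE 0.22). Of 17 antioxidant genes 3 rose (Gpx3, Sod3 and Gpx7), and the signs of the list differed, with a median of -0.0692, a mean of 0.351 and a downward test (camera adjusted p = 0.58). Gpx3, the secreted glutathione peroxidase, had 3890 ± 960 in medulla and 124 ± 86.4 in cortex.

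Double-positive thymocyte genes fell in 13 and rose in 1 of 17 cases (median -2.49, camera adjusted p = 1.4e-12). The log2 fold change was -6.59 (SE 0.22) for Rag2, -5.71 (SE 0.3) for Rag1 and -5.72 (SE 0.16) for Dntt, the terminal transferase that adds junctional nucleotides. Endou, an endoribonuclease, had 215 ± 34 in medulla and 9090 ± 749 in cortex, and Aqp11, an aquaporin, had 108 ± 41.4 and 4640 ± 390. Mature thymocyte genes rose in 16 and fell in 1 of 24 cases (median 1.95, camera adjusted p = 3.3e-09), with Ccr7, the chemokine receptor for entry into the medulla, at 6160 ± 874 against 214 ± 49.5 and Gimap4, a GTPase of lymphocytes, at 20000 ± 2640 against 1490 ± 272. Regulatory T cell genes rose in 7 of 9 cases (camera adjusted p = 0.00059), for example Gpr83 by 2.92 (SE 0.15). Cell cycle genes fell in 25 of 31 cases (median -1.84, camera adjusted p = 5.8e-21), with Ccnb2, a mitotic cyclin, at 1100 ± 282 against 7130 ± 360 and Birc5, survivin, at 1330 ± 170 against 7190 ± 1440. Immediate early genes rose in 12 and fell in 1 of 19 cases (camera adjusted p = 0.00014), with Nr4a3, a nuclear receptor induced by antigen receptor signals, at 2040 ± 249 against 201 ± 38.7. Of the gate markers, Thy1 fell by 2.03 (SE 0.1), Kit rose by 1.66 (SE 0.26), and Cd3e (adjusted p = 0.25) and Ptprc (adjusted p = 0.22) were not called.

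The median log2 fold change of all genes in this comparison was 0.11, and -0.026 after quantile normalization. In fits added after the data were seen, the counts were 2634 higher and 795 lower within the arrays with a wide upper tail and 2250 and 782 within the other arrays. The stricter filter, which tests fewer genes, left 1366 higher.

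The comparison of sorted medullary with sorted cortical thymocytes asked how the lymphoid cells of the compartments differ without stroma. The cortical gate on no or low CD3 selects by maturity, so gate and compartment cannot be told apart for genes that follow maturity. Medullary thymocytes had higher transcripts of mature and regulatory T cells, innate-like T cells, interferon response and MHC class I, and lower transcripts of double-positive cells and of division. Ccr7 had a signal of 9300 ± 934 in medullary and 113 ± 15.8 in cortical thymocytes. Rag2 had 46.3 ± 53.8 and 6850 ± 745. Called genes numbered 1032 higher and 845 lower in medullary thymocytes.

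Mature thymocyte genes rose in 19 of 24 cases (median 2.8, camera adjusted p = 3.5e-21). Gimap4 rose by a log2 fold change of 6.19 (SE 0.13, adjusted p = 8e-29), Ccr7 by 6.07 (SE 0.17, adjusted p = 4e-26), and Klf2, a transcription factor for thymic exit, by 5.22 (SE 0.15, adjusted p = 2e-25). The largest rise was that of Slfn1, a Schlafen family gene, at 4610 ± 748 against 4.36 ± 2.32 (log2 fold change 7.23, SE 0.25). Itgae, the alpha chain of the integrin that binds E-cadherin, had 4960 ± 1380 against 65.8 ± 16.9, and Igfbp4, an insulin-like growth factor binding protein, had 11900 ± 2120 against 159 ± 21.2. Regulatory T cell genes rose in 7 and fell in 1 of 9 cases (camera adjusted p = 2.5e-06), with Gpr83 at 1420 ± 183 against 59.5 ± 21.3 and Il2rb, an IL-2 receptor chain, at 878 ± 202 against 35.8 ± 27.3. Genes of NKT and innate-like T cells rose in 9 and fell in 1 of 12 cases (camera adjusted p = 1.8e-06), with Id2, an inhibitor of E proteins, up by 4.17 (SE 0.13) and Klrd1, the NK receptor chain CD94, up by 4.05 (SE 0.17).

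Double-positive genes fell in 11 and rose in 1 of 17 cases (median -1.82, camera adjusted p = 9.6e-14). The log2 fold change was -6.84 (SE 0.26) for Rag2, -5.16 (SE 0.35) for Rag1 and -4.42 (SE 0.19) for Dntt. Ly6d, a surface antigen, had 228 ± 83.4 in medullary and 9280 ± 875 in cortical thymocytes, and Endou had 212 ± 65.3 and 10800 ± 710. Of 15 genes of double-negative thymocytes 3 rose and 4 fell (camera adjusted p = 0.62): Ptcra, the pre-T cell receptor alpha chain, had 42.4 ± 33.8 against 1600 ± 163, and Il7r, the IL-7 receptor, had 9710 ± 1610 against 411 ± 44. Cell cycle genes fell in 20 of 31 cases (median -1.77, camera adjusted p = 5.1e-22), with Aurkb, a mitotic kinase, at 378 ± 61.7 against 2160 ± 142.

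Interferon-response genes rose in 15 of 17 cases (median 2.63, camera adjusted p = 4.6e-18), with Ifit1 at 3260 ± 563 against 61.8 ± 24.4 and Iigp1, an interferon-inducible GTPase, at 2360 ± 223 against 129 ± 29. MHC class I genes rose in 9 of 13 cases (camera adjusted p = 3.4e-09), with H2-K1 at 29000 ± 7420 against 1680 ± 139. MHC class II genes rose in 6 of 11 cases (camera adjusted p = 6.4e-05). The largest of these was Ctss, the protease cathepsin S, up by 5.5 (SE 0.14), whereas Cd74 had 611 ± 152 against 154 ± 28.8 (1.81, SE 0.17). The TNF and NF-kB list rose in 7 of 15 cases (camera adjusted p = 0.0016), with Tnfsf11, the cytokine RANKL, at 885 ± 213 against 63.7 ± 14.8. Immediate early genes rose in 8 of 19 cases (camera adjusted p = 0.00086), with Egr3 up by 2.81 (SE 0.15).

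Few genes of the macrophage, dendritic cell and B cell lists differed between the sorted groups. Some markers of other lists did differ in mean signal, in both directions. S100a9 had 15.5 ± 17.7 in medullary and 185 ± 84.3 in cortical thymocytes, Pdgfrb 30.7 ± 12.4 and 189 ± 54.4, and Eng 656 ± 138 and 137 ± 43.7. None of 14 macrophage genes was called (camera adjusted p = 0.5), 1 of 12 dendritic cell genes rose (Zbtb46, 121 ± 41.2 against 38.1 ± 22), and of 10 B cell genes 1 rose and 2 fell (camera adjusted p = 0.5). Ighm fell by 1.48 (SE 0.13) in its brightest probe set, but 2 of its 7 probe sets had that direction and with plain-suffix probe sets its log2 fold change was 0.349. Aire was at 40.7 ± 36.5 and 9.86 ± 1.65 and Psmb11 at 17.7 ± 19.2 and 13.9 ± 13.8, neither called. Thy1 fell by 1.06 (SE 0.12), and Cd3e, Ptprc and Kit were not called. In a fit added after the data were seen, the arrays without a wide tail gave 990 higher and 807 lower. No cortical thymocyte array had a wide tail, so no value exists within the wide-tail arrays.

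The interaction term asked which genes differ between the compartments more, or less, in tissue than in sorted thymocytes. Medullary epithelial, tissue-restricted, dendritic, mesenchymal and adhesion genes had a larger medullary excess in tissue, and cortical epithelial and mature thymocyte genes were lower in this difference. Across genes, fold changes of the tissue comparison correlated with those of the thymocyte comparison (Pearson r = 0.574, Spearman rho = 0.556, 13463 genes, which are not independent replicates). Of the 2492 genes higher in whole medulla 706 were also higher in medullary thymocytes (191 if independent), and of the 724 lower genes 479 were also lower (45.4 if independent). The difference itself was called higher for 1698 genes and lower for 299.

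**Figure D2:**
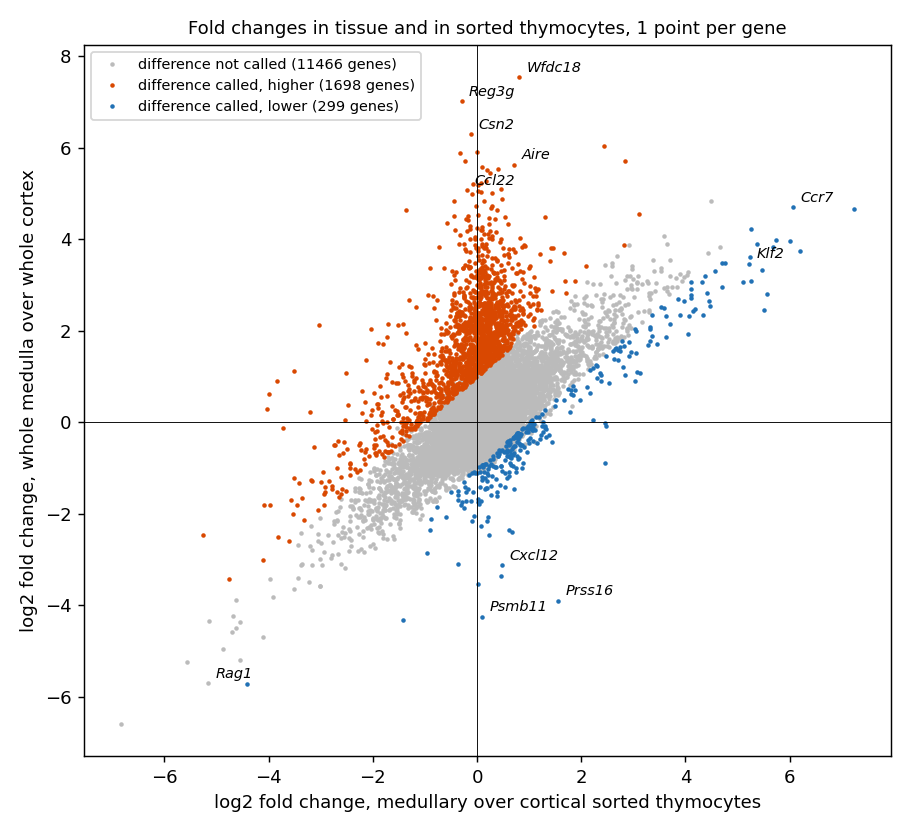
Log2 fold change of whole medulla over whole cortex (vertical) against that of medullary over cortical sorted thymocytes (horizontal), 1 point per gene, coloured by whether the difference between both was called. Csn2, Reg3g, Aire and Ccl22 are high in the tissue comparison and were not called in thymocytes, and Rag1 is low in both.

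Of 14 medullary epithelial genes 13 had a higher difference (median 2.47, camera adjusted p = 5.3e-14), with 4.92 (SE 0.38, adjusted p = 1.3e-12) for Aire and 4.57 (SE 0.28, adjusted p = 2.1e-15) for Spib, an Ets family transcription factor. Tissue-restricted antigens had it in 18 of 21 cases (camera adjusted p = 5.3e-14), with 7.32 (SE 0.31) for Reg3g and 6.41 (SE 0.4) for Csn2. Wfdc18 had 6.73 (SE 0.4), and Ptgs2, the inducible cyclooxygenase, had 6.2 (SE 0.31). Of 14 cortical epithelial genes 8 had a lower and 1 a higher difference (median -2.06, camera adjusted p = 2.1e-07), with -5.45 (SE 0.19) for Prss16, -4.35 (SE 0.28) for Psmb11, -3.61 (SE 0.21) for Cxcl12 and -3.07 (SE 0.14) for Ccl25, a chemokine of cortical epithelium, the last in 1 of 2 probe sets. Inmt, a methyltransferase, had -3.82 (SE 0.26).

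Dendritic cell genes had a higher difference in 7 of 12 cases, or 8 adjusted over the list alone (camera adjusted p = 3.6e-07), with 5.26 (SE 0.31) for Ccl22 and 5.19 (SE 0.23) for Fscn1. Mesenchymal genes had it in 11 of 19 cases (camera adjusted p = 2.1e-07), for example Pdgfrb, a growth factor receptor of pericytes and fibroblasts, with 3.65 (SE 0.29). Pdgfrb had 763 ± 159 in whole medulla and 221 ± 99.3 in whole cortex. A fall in sorted cells added to its difference, with 30.7 ± 12.4 in medullary and 189 ± 54.4 in cortical thymocytes. Basement membrane and adhesion genes had it in 11 of 18 cases, or 12 adjusted over the list alone (camera adjusted p = 4.2e-07), with 3.02 (SE 0.36) for Itgb4, an integrin of epithelial attachment. Chemokine genes were higher in 11, or 12 adjusted over the list alone, and lower in 3 of 18 cases (camera adjusted p = 0.0011), but not with an estimated correlation (adjusted p = 0.078 with an estimated correlation). Mature thymocyte genes had a lower difference in 6 of 24 cases (median -0.725, camera adjusted p = 3.2e-08), with -2.45 (SE 0.18) for Gimap4, -1.76 (SE 0.2) for Klf2 and -1.37 (SE 0.22) for Ccr7. Of 31 cell cycle genes 1 was called, Pcna, a clamp of DNA replication, at -1.33 (SE 0.17). The list was lower (camera adjusted p = 0.022), but not with an estimated correlation (adjusted p = 0.45 with an estimated correlation), after quantile normalization or with plain-suffix probe sets. The interferon list did not differ by the test (camera adjusted p = 0.32), with 2 of 17 genes called lower, Ifit1 at -2.17 (SE 0.2) and Oasl2 at -1.16 (SE 0.24). Isg20, an interferon-induced exonuclease, had -3.35 (SE 0.14).

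In a fit added after the data were seen, the arrays without a wide tail gave 1209 higher and 183 lower, and the stricter filter, which tests fewer genes, left 881 higher.

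The cortical subregions were compared to ask how expression changes along the path from the capsule to the medulla. In subcapsular cortex, against central cortex, mesenchymal and cell cycle genes were higher and mature thymocyte and immediate early genes lower. Col3a1, a fibrillar collagen, had 2180 ± 353 in subcapsular and 426 ± 66.7 in central cortex. Cd69, an early activation marker, had 482 ± 62.5 and 1420 ± 268. Called genes numbered 114 higher and 60 lower in subcapsular cortex.

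Mesenchymal genes rose in 8 of 19 cases (median 0.859, camera adjusted p = 8.6e-12), with Col3a1 up by a log2 fold change of 2.29 (SE 0.25, adjusted p = 1.6e-07), Col1a2 by 2.15 (SE 0.23, adjusted p = 1.2e-07) and Dcn, decorin, by 1.69 (SE 0.33, adjusted p = 0.001). Among the largest rises were Car3, a carbonic anhydrase, at 871 ± 502 against 14.3 ± 8.99, Ogn, osteoglycin, at 396 ± 56.6 against 12.2 ± 5.44, Aldh1a3, an enzyme of retinoic acid synthesis, at 230 ± 33.3 against 13.3 ± 20.2, and Efemp1, a fibulin, at 261 ± 96 against 17.3 ± 11.9. Cell cycle genes rose in 3 of 31 cases (median 0.654, camera adjusted p = 7.2e-16): Ccne2, an S phase cyclin, at 1810 ± 328 against 763 ± 45.2, Aurkb at 1430 ± 314 against 666 ± 21.7, and Cdc6, a replication licensing factor, at 2910 ± 349 against 1410 ± 139. Of 15 double-negative genes 1 rose, Il2ra, the IL-2 receptor alpha chain, at 789 ± 141 against 290 ± 61.5. That list passed at the preset correlation (camera adjusted p = 0.042), but not otherwise (adjusted p = 0.16 with an estimated correlation), and it lost its call with the smaller offset, the stricter filter and plain-suffix probe sets. Of 7 myeloid and granulocyte genes 1 rose, or 5 adjusted over the list alone (camera adjusted p = 0.00083, adjusted p = 0.15 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, had 1820 ± 745 against 642 ± 694.

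Mature thymocyte genes fell in 4 of 24 cases (median -0.448, camera adjusted p = 3e-08), with Cd69 down by -1.5 (SE 0.2), Gimap4 at 542 ± 13.7 against 1530 ± 104 and Ccr7 at 32.6 ± 24.7 against 112 ± 15.9. Immediate early genes fell in 4 of 19 cases (median -0.358, camera adjusted p = 1e-05): the zinc finger genes Egr1 (2630 ± 448 against 5790 ± 464), Egr2 (log2 fold change -1.43, SE 0.17) and Egr3 (1 of its 2 probe sets in that direction), and Nr4a3 (130 ± 31.1 against 303 ± 35.3). Trav6-3, a T cell receptor alpha variable segment, had 193 ± 15.7 against 738 ± 30.2, and Cd5l, a protein secreted by macrophages, had 88.8 ± 9.49 against 367 ± 80.1. None of 14 macrophage genes was called, although the list was lower (median -0.312, camera adjusted p = 0.00083). No gene of the Notch list (camera adjusted p = 0.071, Notch1 4600 ± 274 against 3210 ± 34.7) or of the cortical epithelial list (camera adjusted p = 0.13, Psmb11 3510 ± 120 against 2190 ± 449) was called. Both lists were called higher when only the groups compared were fitted (mean log2 fold change 0.25 and 0.219). Cd3e, Thy1, Ptprc, Kit and Aire were not called either.

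Transcripts that depend on sex differed beside these groups. Xist, the RNA that silences an X chromosome in females, was high in all 9 subregion arrays although the labels say male, with 9640 ± 445 in subcapsular, 12000 ± 1060 in central and 11000 ± 795 in perimedullary cortex, against means of 51.7 to 140 in the other groups. The order of the subregions differed between its probe sets, with 3960 ± 565, 3180 ± 1810 and 2440 ± 1240 in the dimmest. The Y-linked gene Eif2s3y had 866 ± 345 in subcapsular, 10 ± 12.2 in central and 807 ± 165 in perimedullary cortex, and means of 2060 to 2550 elsewhere. Against central cortex it was called higher in subcapsular (log2 fold change 4.59, SE 0.23) and perimedullary cortex (4.55, SE 0.23), as were the Y-linked genes Kdm5d (3.29, SE 0.22, and 3.09, SE 0.22) and Uty (2.42, SE 0.28, and 2.38, SE 0.28). None of these was called between perimedullary and subcapsular cortex.

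**Figure D3:**
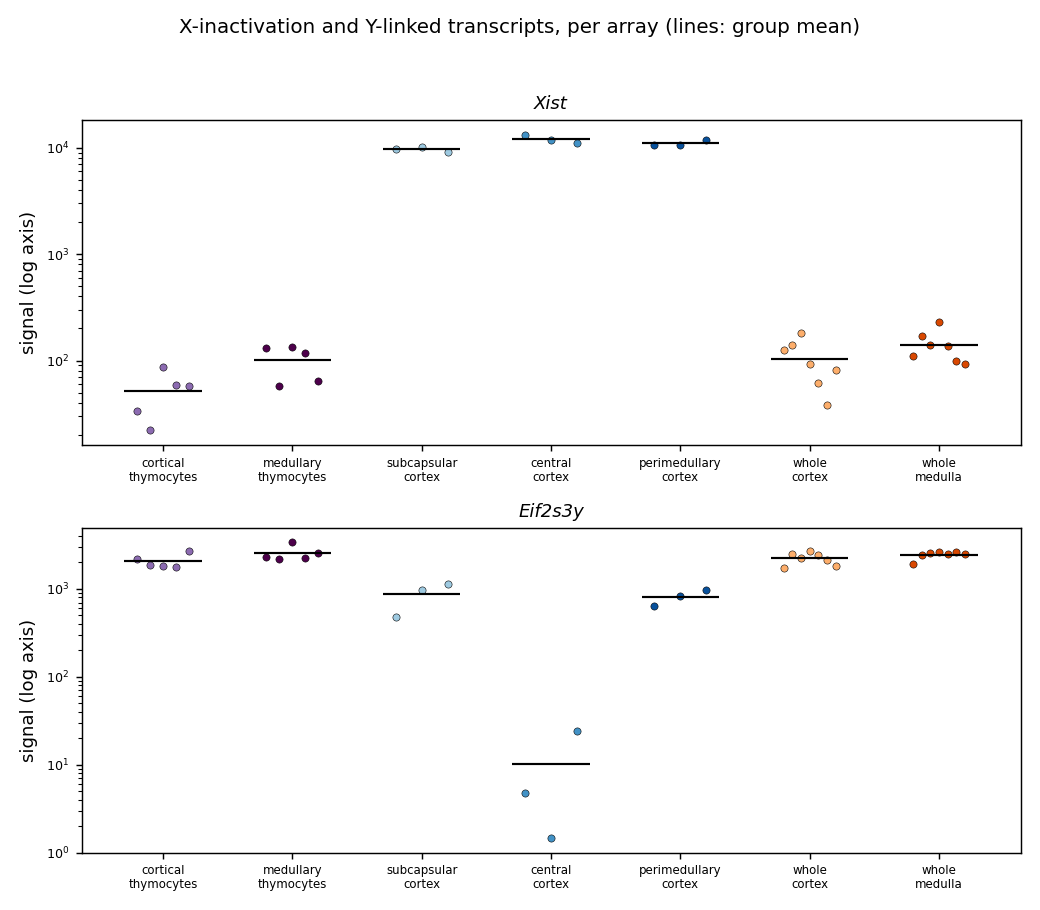
Signal of Xist and of the Y-linked gene Eif2s3y on a log axis, 1 point per array in the 7 groups, with a line at each group mean. Xist is high in the 9 subregion arrays, and Eif2s3y is lowest in central cortex at 10 ± 12.2 (SD, n = 3).

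Without central cortex replicate 2 the count of genes higher in subcapsular cortex was 75. The count of lower genes was 91 when only the groups compared were fitted and 96 with array weights.

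In perimedullary cortex, against central cortex, genes of mature thymocytes, interferon response, MHC class II, dendritic cells, macrophages and B cells were higher. Itgae had 2390 ± 329 in perimedullary and 255 ± 33.9 in central cortex. Ms4a1 had 686 ± 117 and 73.1 ± 28.7. Called genes numbered 176 higher and 5 lower, the Y-linked genes above being among the higher.

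Mature thymocyte genes rose in 10 of 24 cases (median 0.809, camera adjusted p = 3.1e-25), with Ms4a4b, a membrane protein of T cells, at 5730 ± 290 against 1250 ± 77.5, Gimap4 at 6960 ± 273 against 1530 ± 104 and Ccr7 at 646 ± 51.6 against 112 ± 15.9. Interferon-response genes rose in 8 of 17 cases (median 0.877, camera adjusted p = 7.2e-28), with Oas1a, an oligoadenylate synthetase, up by a log2 fold change of 2.25 (SE 0.34), Rsad2, viperin, by 1.79 (SE 0.23) and Irf7, an interferon regulatory factor, by 1.73 (SE 0.21). Dendritic cell genes rose in 4 of 12 cases, or 5 adjusted over the list alone (camera adjusted p = 1.5e-08), with Ccl22 at 224 ± 30.7 against 63.3 ± 35.2 and Itgax, CD11c, at 426 ± 34.4 against 158 ± 2.34. Fscn1, up by 1.27 (SE 0.23), did so in 1 of 3 probe sets and had -0.143 with plain-suffix probe sets. B cell genes rose in 3 of 10 cases, or 4 adjusted over the list alone (camera adjusted p = 8.7e-07), with Ms4a1 up by 2.87 (SE 0.28) and Cd22, a B cell lectin, by 2.1 (SE 0.29). MHC class II genes rose in 3 of 11 cases (camera adjusted p = 1.2e-14), with H2-Ob at 1340 ± 266 against 356 ± 97 and Ctss at 7500 ± 397 against 2790 ± 334.

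Of 14 macrophage genes 2 rose and 1 fell (median 0.564, camera adjusted p = 5.2e-08): Lyz2 had 3960 ± 258 against 1160 ± 12.2, Csf1r, the receptor for macrophage colony-stimulating factor, had 6760 ± 757 against 3210 ± 519, and Cd163 had 82.9 ± 13.1 against 348 ± 180. Chemokine genes rose in 4 of 18 cases (camera adjusted p = 2.3e-05), with Ccl8 up by 2.67 (SE 0.35). Ccl9 rose by 1.22 (SE 0.33) in 1 of 2 probe sets. The further largest rises were those of Ccl12, a monocyte chemokine, at 202 ± 46 against 5.24 ± 1.95 and Pla2g2d, a secreted phospholipase, at 1580 ± 11.3 against 214 ± 64.4. Of 14 medullary epithelial genes 1 rose, or 2 adjusted over the list alone (median 0.24, camera adjusted p = 0.0099): Fezf2 had 66.2 ± 12.2 against 17.2 ± 12.5, and Aire, at 122 ± 21.7 against 42.1 ± 22.8, was not called (adjusted p = 0.11). Of 21 tissue-restricted antigens 1 rose, Csn2 at 173 ± 7.72 against 3.03 ± 0.709 (camera adjusted p = 0.028, adjusted p = 0.13 with an estimated correlation), and the list lost its call with the smaller offset, the mean of the probe sets and plain-suffix probe sets. No cortical epithelial gene was called (median -0.00613, camera adjusted p = 0.85, Psmb11 1660 ± 89.5 against 2190 ± 449), and neither were Cd3e, Thy1, Ptprc and Kit.

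The 5 genes that fell were Cd163, Glrb (a glycine receptor subunit, 6.2 ± 3.75 against 78.1 ± 36.2), Khdc1a (2.52 ± 0.892 against 53.7 ± 20.2), Tmem97 (58.3 ± 51.2 against 159 ± 19.1) and Cd5l (149 ± 83.6 against 367 ± 80.1). Their number was 3 with the smaller offset, 2 with the stricter filter, 10 with array weights, 1 without central cortex replicate 1, 2 without central cortex replicate 3, 3 without perimedullary cortex replicate 1 and 2 without perimedullary cortex replicate 3.

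Perimedullary against subcapsular cortex spans the full depth of the cortex and had the most called genes of the subregion comparisons, 392 higher and 223 lower in perimedullary cortex. Mature thymocyte, macrophage, dendritic cell and protease genes were higher, and cell cycle and mesenchymal genes lower. Gimap4 had 6960 ± 273 in perimedullary and 542 ± 13.7 in subcapsular cortex. Cdc6 had 1230 ± 191 and 2910 ± 349.

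**Figure D4:**
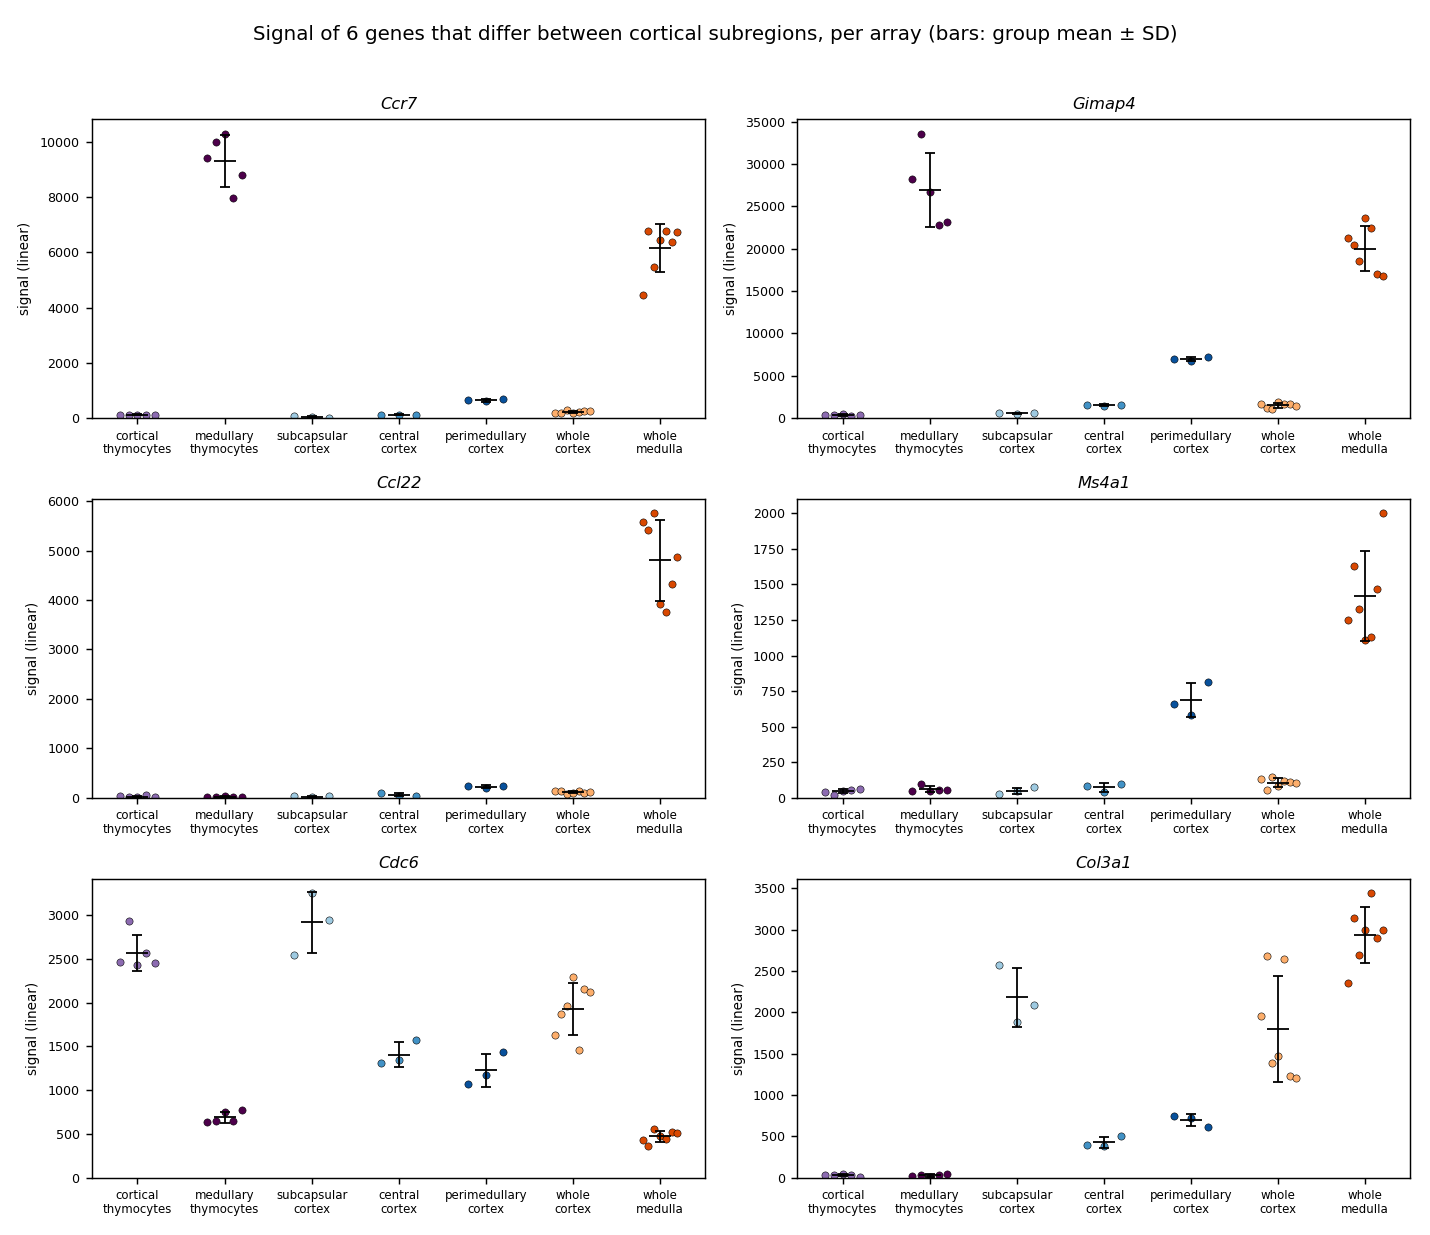
Signal of 6 genes on a linear axis, 1 point per array in the 7 groups, with bars for the group mean and SD. In the cortical subregions, Ccr7, Gimap4, Ccl22 and Ms4a1 are highest in perimedullary cortex, and Cdc6 and Col3a1 are highest in subcapsular cortex.

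Mature thymocyte genes rose in 16 of 24 cases (median 1.16, camera adjusted p = 1e-21), with Gimap4 up by a log2 fold change of 3.62 (SE 0.17, adjusted p = 3.6e-17), Ccr7 by 3.61 (SE 0.22, adjusted p = 9.1e-15) and Ms4a4b by 2.91 (SE 0.16, adjusted p = 5.7e-16). Itgae had 2390 ± 329 against 178 ± 11.6. Macrophage genes rose in 7 and fell in 1 of 14 cases (median 1, camera adjusted p = 3.1e-09), with C1qc, a complement component, at 1220 ± 218 against 437 ± 42.5, Timd4, a receptor for apoptotic cells, at 262 ± 33.7 against 67.3 ± 8, and Cd163 at 82.9 ± 13.1 against 379 ± 30.2. Dendritic cell genes rose in 6 of 12 cases (median 1.05, camera adjusted p = 1e-07), with Ccl22 at 224 ± 30.7 against 26.6 ± 14.3 and Itgax at 426 ± 34.4 against 117 ± 15. Fscn1, up by 2.34 (SE 0.23), did so in 1 of 3 probe sets and had -0.00865 with plain-suffix probe sets. Of 18 lysosomal and thymic protease genes 4 rose and 1 fell (camera adjusted p = 7.2e-07), with Ctsh, cathepsin H, at 1550 ± 97.7 against 320 ± 30.2 and Ctss at 7500 ± 397 against 2510 ± 103. Pla2g2d rose by 3.68 (SE 0.31), and Clec7a, the beta-glucan receptor dectin-1, had 1650 ± 139 against 159 ± 19.9.

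Cell cycle genes fell in 12 of 31 cases (median -0.856, camera adjusted p = 7.3e-19), with Aurkb at 439 ± 90.7 against 1430 ± 314, Plk1, a mitotic kinase, at 431 ± 118 against 1350 ± 198 and Ccne2 at 644 ± 98.8 against 1810 ± 328. Mesenchymal genes fell in 4 of 19 cases (median -0.533, camera adjusted p = 0.0025), with Col14a1 at 49.8 ± 10.6 against 352 ± 45.9 and Col3a1 at 693 ± 71.3 against 2180 ± 353. Car3 had 17.4 ± 19.6 against 871 ± 502, Ogn 15.5 ± 15.3 against 396 ± 56.6, and Dpep1, a membrane dipeptidase, 45.2 ± 51.8 against 292 ± 45.3. Of 14 cortical epithelial genes 1 fell, Psmb11 (1660 ± 89.5 against 3510 ± 120, log2 fold change -1.07, SE 0.27), and the list did not pass (camera adjusted p = 0.16), although it was called lower when only the groups compared were fitted (mean log2 fold change -0.25). Aire rose by 1.1 (SE 0.38, adjusted p = 0.039). No Wnt gene was called, and the signs of that list differed, with a median of -0.0436, a mean of -0.0251 and an upward test (camera adjusted p = 0.95). The 2 erythroid genes likewise had a median and mean of -0.384 and an upward test (camera adjusted p = 0.64), which was called higher with plain-suffix probe sets (mean 0.749), although 1 of them fell, Alas2, of haem synthesis, at 9.1 ± 1.14 against 77.7 ± 29. None of 4 adipocyte genes was called (camera adjusted p = 0.6), and Cd3e, Thy1, Ptprc and Kit were not.

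Across genes, these fold changes correlated with those of whole medulla over whole cortex (Pearson r = 0.452, Spearman rho = 0.424, 13463 genes) and with those of medullary over cortical thymocytes (r = 0.432, rho = 0.345), genes again not being independent replicates. Of the 392 genes higher in perimedullary cortex 317 were also higher in whole medulla (72.6 if independent), and of the 223 lower genes 120 were also lower there (12 if independent). No subregion array had a wide tail.

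Whole cortex was compared with sorted cortical thymocytes to ask which transcripts of the tissue come with its other cells. Cortical epithelial, macrophage, mesenchymal, MHC class II and chemokine genes were far higher in the tissue, and of the double-positive and cell cycle genes 1 was called. Prss16 had 14000 ± 1370 in cortex and 44.5 ± 15.5 in sorted cells. Called genes numbered 1288 higher and 203 lower in whole cortex.

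Of 14 cortical epithelial genes 13 rose (median 6.11, camera adjusted p = 5.9e-24). Tbata, a gene of thymic epithelium, had 22700 ± 3770 against 15.6 ± 14.7 (log2 fold change 9.14, SE 0.18), Cxcl12 had 7970 ± 395 against 19.9 ± 15.1, Psmb11 rose by 6.16 (SE 0.19), and Ccl25 had 17700 ± 2230 against 86.4 ± 23.9, the last in 1 of 2 probe sets. Macrophage genes rose in 13 of 14 cases (median 4.44, camera adjusted p = 1.4e-23), with C1qa at 1860 ± 372 against 4.97 ± 2.93 and Vcam1, an adhesion molecule, at 4070 ± 335 against 4.77 ± 1.48. Mesenchymal genes rose in 16 of 19 cases (camera adjusted p = 3.6e-13), with Sparc, a matrix glycoprotein, at 542 ± 73.9 against 7.29 ± 2.94. MHC class II genes rose in 9 of 11 cases (camera adjusted p = 3.4e-14), with H2-Aa at 9090 ± 1150 against 155 ± 54.9. Chemokine genes rose in 13 of 18 cases (camera adjusted p = 1.8e-09), with Cxcl10 at 460 ± 138 against 27.1 ± 17.1. All 7 myeloid and granulocyte genes rose (camera adjusted p = 0.00029, adjusted p = 0.098 with an estimated correlation), with S100a8, the partner of S100a9, at 4960 ± 3210 against 269 ± 127. Adipocyte genes rose in 3 of 4 cases (camera adjusted p = 4.7e-05), with Fabp4, a fatty acid binding protein, at 3100 ± 714 against 16.3 ± 11.8. Medullary epithelial genes rose in 6 of 14 cases (camera adjusted p = 0.00019), with Krt17 at 651 ± 209 against 19.1 ± 13.2, whereas Aire was not called (25.3 ± 24.2 against 9.86 ± 1.65).

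Of 17 double-positive genes 1 fell, Cd4 (2430 ± 1050 against 5700 ± 1500), and of 31 cell cycle genes none was called (Pcna 39500 ± 9020 against 24600 ± 671). Neither list passed (camera adjusted p = 0.24 and 0.94), but the double-positive list was called lower after quantile normalization (mean log2 fold change -0.431), with the mean of the probe sets (-0.328) and with plain-suffix probe sets (-0.27). Other genes with large falls were H3f3b, a histone variant gene, at 58.4 ± 36.3 against 377 ± 114, Vps33b, of vesicle sorting, at 93.8 ± 75.1 against 428 ± 146, and Atxn7l2 at 136 ± 102 against 546 ± 60. Thy1, Ptprc, Kit and Cd3e were not called. In fits added after the data were seen, the arrays without a wide tail, which leave 2 of whole cortex, gave 1240 genes higher and 27 lower, 12 of the 27 being among the 203, and with a wide-tail term 49 were lower. With the stricter filter, which tests fewer genes, 764 were higher.

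The same question for the medulla compared whole medulla with sorted medullary thymocytes. Epithelial, dendritic, macrophage, mesenchymal, endothelial and adhesion genes were higher in the tissue and mature thymocyte genes lower. Lyz1, a lysozyme, had 21100 ± 1900 in medulla and 33.5 ± 33 in sorted cells. Called genes numbered 2605 higher and 162 lower in whole medulla, and 1019 of the higher genes were also higher in whole cortex than in its thymocytes (249 if independent).

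All 14 medullary epithelial genes rose (median 4.8, camera adjusted p = 1.2e-12), with Krt5, a basal keratin, at 6110 ± 500 against 109 ± 28 and Aire up by a log2 fold change of 5.32 (SE 0.27, adjusted p = 8.3e-19). Tissue-restricted antigens rose in 19 of 21 cases (camera adjusted p = 1.3e-10), with Csn2 up by 7.14 (SE 0.28). All 12 dendritic cell genes rose (median 3.26, camera adjusted p = 2.1e-08), with Fscn1 up by 8.06 (SE 0.16) and Ccl17, a ligand of CCR4, up by 4.54 (SE 0.26). Macrophage genes rose in 12 of 14 cases (camera adjusted p = 1.2e-12), with Mpeg1, perforin-2, at 6510 ± 855 against 13.2 ± 5.73. Mesenchymal genes rose in 17 of 19 cases (camera adjusted p = 3.6e-14), with Col6a1 at 2360 ± 303 against 21.4 ± 17.9, and endothelial genes in 10 of 13 (camera adjusted p = 0.0025, not called with the stricter filter, which tests fewer genes), with Plvap, of fenestrated endothelium, at 655 ± 129 against 38.6 ± 15. Rgs5, a pericyte gene, had 11300 ± 802 against 17 ± 19.6. Chemokine genes rose in 16 of 18 cases (camera adjusted p = 8.5e-12), with Ccl11, eotaxin, at 1110 ± 273 against 8.28 ± 7.32. Basement membrane and adhesion genes rose in 16 of 18 cases (camera adjusted p = 8.5e-12), with Col4a1 at 2680 ± 580 against 55.5 ± 20.2. Dsp, desmoplakin, had 8320 ± 1370 against 18.2 ± 21, and Ubd, a ubiquitin-like protein, had 14000 ± 3190 against 36.3 ± 23.2. B cell genes rose in 7 of 10 cases (camera adjusted p = 0.0016), with Ms4a1 at 1420 ± 317 against 61.5 ± 19. Jchain, the joining chain of polymeric antibodies, had 644 ± 150 against 76.9 ± 17.8, but it was higher still in whole cortex, at 3010 ± 1240.

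Mature thymocyte genes fell in 4 of 24 cases (median -0.573, camera adjusted p = 7.5e-06): Ccr4, a chemokine receptor (84.3 ± 30.5 against 292 ± 125), the surface receptors Cd5 (5470 ± 1370 against 12300 ± 1300) and Cd6 (2720 ± 610 against 6910 ± 1420), and S1pr1, the exit receptor for sphingosine 1-phosphate (1020 ± 191 against 2090 ± 295). Gzma, a granzyme, had 315 ± 60.4 against 1690 ± 442, and Cpa3, a mast cell protease, had 28.1 ± 14 against 283 ± 118. Cd3e fell by 1.24 (SE 0.23), Psmb11 rose by 1.81 (SE 0.19), and Thy1, Ptprc and Kit were not called. In fits added after the data were seen, the counts were 2616 higher and 222 lower within the wide-tail arrays and 2453 and 129 within the others. Lower genes numbered 332 after quantile normalization, and 1233 were higher with the stricter filter, which tests fewer genes.

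The mean of the 3 subregions was set against whole cortex to measure how far separate dissections of a compartment differ. Called genes numbered 948 higher and 926 lower in the subregions. Other probe sets of the higher genes had a median log2 fold change of 0.00818 and the same direction in 50.8% of cases, and those of the lower genes -0.284 and 58.7%, where 84% to 97.2% had the same direction in the other comparisons. The values below are therefore those of single probe sets. Xist was the largest rise (log2 fold change 6.48, SE 0.2, in 3 of 3 probe sets), and Eif2s3y (-2.94, SE 0.14), Kdm5d (-2.15, SE 0.14) and Uty (-2.29, SE 0.17) were lower.

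Ctse, the protease cathepsin E, was at 7240 ± 786 in subcapsular, 9980 ± 449 in central and 8090 ± 429 in perimedullary cortex and 435 ± 116 in whole cortex, in 1 of 2 probe sets. Armc8 rose by 4.41 (SE 0.22) in 4 of 5 probe sets, Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, by 4.75 (SE 0.4) in 2 of 5, and Boll by 4.74 (SE 0.35) and Nrip2 by 4.06 (SE 0.61) in 1 of 2 each. The largest fall was that of AY036118 at -5.37 (SE 0.37). It had 47400 ± 18000 in whole cortex, 29700 ± 19100 in whole medulla, 7220 ± 4560 in sorted cortical thymocytes and 856 ± 216 in subcapsular cortex. Further falls included Cd8b1, the CD8 beta chain, at -3.72 (SE 0.11), with 30000 ± 7420 in whole cortex and 2120 ± 73.6 in subcapsular cortex. Ndufs5, of respiratory complex I, had -3.59 (SE 0.1), and Ube2s, a ubiquitin-conjugating enzyme, had -3.59 (SE 0.12). Of 13 MHC class I genes 3 fell (camera adjusted p = 0.035, adjusted p = 0.48 with an estimated correlation), among them Pdia3, of the peptide-loading complex, at -3.67 (SE 0.11) and Psmb9, an immunoproteasome subunit, at -1.58 (SE 0.1). Of 17 double-positive genes 2 rose and 4 fell (camera adjusted p = 0.035, adjusted p = 0.48 with an estimated correlation), with Dntt at -1.37 (SE 0.15) and Rag1 at -1.39 (SE 0.28), which had 0.0664 after quantile normalization. Of 31 cell cycle genes 2 rose and 3 fell (camera adjusted p = 0.035, adjusted p = 0.8 with an estimated correlation), with Pcna at -1.89 (SE 0.1). These 3 lists lost their calls after quantile normalization and with the stricter filter. Ccne1 (1.25, SE 0.1) and Mcm2 (1.2, SE 0.13), both of DNA replication, rose in 1 of 2 probe sets each and had -0.412 and -0.872 with plain-suffix probe sets. Ptprc fell by 1.13 (SE 0.12) in 1 of 2 probe sets, with 0.271 after quantile normalization and 1.11 with plain-suffix probe sets, and Cd3e, Thy1, Kit, Aire and Psmb11 were not called. With the mean of the probe sets of a gene 481 genes were higher. In a fit added after the data were seen, the arrays without a wide tail gave 811 higher and 1064 lower.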

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

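The tests of Xist over its probe sets, of the sex of the donors, of the sex makeup of the dissected pools, of carry-over over all lists and by list, of the wide-tail arrays as a batch and of the correlation between probe sets in the subregions against whole cortex were chosen after the results they concern were seen. For the genes lower in whole cortex than in its thymocytes, the tests of disagreement between probe sets and of lowered signal on wide-tail arrays were chosen before their own values were seen. Several values stand out or need care, and 3 patterns are weighed here.

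Xist was high and Y-linked transcripts were low or absent in the cortical subregion arrays, although the labels call all mice male. A fault of 1 Xist probe set is argued against, since in each of the Xist probe sets the lowest subregion array exceeded the highest other array, by a ratio of at least 11.5. Female or mixed-sex donors could account for both, since in the analysed probe set of each Y-linked gene, its brightest, all subregion arrays lay below all other arrays, by a ratio of at most 0.955. In 5 of all 9 Y-linked probe sets some arrays overlapped, by a ratio up to 13.4, but these were the dimmer ones and pools of both sexes would keep a part of the Y-linked signal, so this does not count against such donors. A different sex makeup of the pools is argued against as the whole cause of the 615 genes called between perimedullary and subcapsular cortex, where no Y-linked gene was called, while for the comparisons with central cortex it stays open.

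Transcripts of mature thymocytes, dendritic cells and B cells were higher in perimedullary than in central cortex. Sex makeup is argued against, since these lists were also higher against subcapsular cortex, with camera adjusted p up to 6.8e-06. Medullary tissue carried over with its average composition should bring epithelial transcripts in the same share. Shares of the medullary signal were taken for the listed genes called higher in whole medulla than in whole cortex. The median share was 2.09% for 31 epithelial and tissue-restricted genes and 20.4% for 32 genes of the other lists, a ratio of 9.79 (interval 5.64 to 21.7). The ratio was 11.1 (7 to 24.5) for mature thymocyte and 5.65 (2.52 to 15.1) for dendritic cell genes alone, which argues against such carry-over for the medians of these 2 lists. The intervals come from draws of genes, which are not independent replicates. They leave out the spread between arrays and may be too narrow. Each share also sets subregion arrays against whole-tissue arrays. These sets differed in sex-linked transcripts, and fold changes of 2 probe sets of a gene correlated at 0.15 between subregions and whole cortex. The shares may therefore not be on 1 scale. For the 6 B cell genes, with 16.6 (-0.568 to 122), carry-over cannot be told apart from other sources as the genes are few. Their shares ran from -12.7% (Fcrla) to 249% (Cd22). Cd22 had 763 ± 191 in perimedullary cortex, above its 389 ± 52.3 in whole medulla, but 1 gene does not decide for the list. Carry-over also stays open for single dendritic genes such as Cd209a (3.03%), Ccl22 (3.43%), Fscn1 (5.27%) and Ccl17 (8.21%). Shares in the epithelial set ranged to 25.2% (Trp63) and 24.7% (Cd80) and held Aire (3.46%) and Spib (5.6%). Trp63 was, however, highest among the subregions in subcapsular cortex (1000 ± 98.1), and the next share after Trp63 and Cd80 was 6.11% (Krt5). Carry-over of thymocyte-rich medulla alone and a true gradient of these cells towards the medulla both stay open as hypotheses, and high signals on the subregion arrays may be compressed.

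Of the 203 genes lower in whole cortex than in sorted cortical thymocytes, 12 were still called lower within the arrays without a wide tail, so that the wide-tail arrays as a batch may account for most of these calls, although only 2 whole cortex arrays remain there. The median log2 fold change of the 203 genes was -1.2 over all arrays, -0.45 within the arrays without a wide tail and -0.81 with a wide-tail term. Whether the signal of these genes is lowered on wide-tail arrays in general cannot be told apart from differences between samples, since the median log2 difference of wide-tail and other arrays was -0.2 in medullary thymocytes, -0.46 in whole medulla and -1.1 in whole cortex. Disagreement between probe sets is argued against by a median of -0.72 for the other probe sets of these genes. For the 3 subregions against whole cortex, a probe-level or labelling difference between the sets of arrays may account for many calls, since 2 probe sets of a gene correlated at 0.15 there against 0.805 in whole medulla against whole cortex, a share of 0.186. Between pairs of subregions this correlation was 0.485 to 0.557, and in the remaining comparisons 0.687 to 0.819.

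Other splits of the same arrays were counted for each comparison. Of 100 splits, 1, the real one, gave as many genes for whole medulla against whole cortex (3216, highest other 2131), medullary against cortical thymocytes (1877, highest other 817), whole cortex against its thymocytes (1491, highest other 1080), whole medulla against its thymocytes (2767, highest other 2066) and the subregions against whole cortex (1874, highest other 866). A random division of these arrays is thus an unlikely source of these counts. Such splits cannot tell group from batch or address shared animals. For the difference between tissue and thymocytes, 3 of 100 splits, the real one included, gave at least the real 1997, the highest other giving 3317. That share is under 0.05 but is not adjusted over the 9 comparisons, so it does not exclude chance. The other splits with more genes than the real one keep 12 of the 14 tissue arrays and 2 of the 10 sorted arrays in their group, so that the compartment differences add up, a structure of the samples. For the subregion pairs the 10 splits are too few for a share under 0.05, with 174 genes for subcapsular against central (highest other 1), 181 for perimedullary against central (highest other 9) and 615 for perimedullary against subcapsular (highest other 8).

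The compartment difference was itself different between tissue and sorted thymocytes for 1698 genes in the higher and 299 in the lower direction. Arrays far from the others of their group were looked for in whole cortex, whole medulla and the sorted thymocyte groups. List means, array measures and a part of the named genes were used, and no other values were searched. The cortical subregions were left out, so outlying arrays there are not covered. Nrip2, for example, had 14300 ± 22500 in central cortex. The search found 5 of 116 list means (5.8 by chance), 1 of 12 array measures (0.6 by chance) and 25 of 348 gene values (17.4 by chance). All values that follow are on the log2 scale, with the range of the other arrays of the group in brackets.

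Among list means, antioxidant enzymes had 10.13 in medullary thymocyte replicate 3 (9.911 to 9.951) and erythroid cells 7.7 in replicate 2 (6.891 to 6.993). Basement membrane and adhesion had 7.983 in whole cortex replicate 5 (8.271 to 8.405). In cortical thymocytes, dendritic cells had 5.439 in replicate 5 (5.738 to 5.835) and the Notch pathway 7.909 in replicate 2 (8.132 to 8.187). The median signal of medullary thymocyte replicate 5 was 6.359 (6.652 to 6.697).

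In medullary thymocytes, replicate 1 had 7.391 for Aqp11 (7.997 to 8.071), 5.881 for Csn2 (4.951 to 5.133) and 7.26 for Rag1 (9.784 to 10.67). Replicate 2 had 6.106 for Glrb (4.81 to 4.945), 6.918 for Ms4a1 (6.221 to 6.393) and 5.24 for Ptgs2 (4.791 to 4.823). Replicate 3 had 12.86 for Itgae (11.97 to 12.18) and 5.546 for Khdc1a (4.795 to 4.896), and replicate 4 had 4.892 for Reg3g (5.158 to 5.201). In cortical thymocytes, replicate 4 had 5.859 for Dpep1 (4.984 to 5.073), 13.23 for Endou (13.41 to 13.47) and 11.69 for Ndufs5 (11.89 to 11.95), and replicate 5 had 5.35 for Boll (6.229 to 6.487), 5.249 for Efemp1 (4.798 to 4.914) and 6.927 for Itgae (6.346 to 6.458).

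In whole medulla, replicate 1 had 10.92 for Eif2s3y (11.25 to 11.38), 15.13 for Fscn1 (14.11 to 14.5) and 11.66 for Pdia3 (12.19 to 12.44), replicate 3 had 10.25 for Dntt (8.948 to 9.485), replicate 4 had 5.552 for Boll (6.928 to 7.673) and replicate 5 had 9.271 for Prss16 (9.802 to 10.14). In whole cortex, replicate 2 had 5.714 for Aldh1a3 (6.744 to 7.214) and 9.953 for Trav6-3 (9.224 to 9.534), replicate 3 had 10.09 for Hadha (10.62 to 11.01) and replicate 5 had 5.267 for Slfn1 (6.582 to 7.427).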

How the results depend on the processing

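The wide-tail term and the fits within sets of arrays were chosen after the data were seen. Where no cause is named for a change below, the cause was not tested. The stricter filter tests fewer genes and so left 1366 genes higher in whole medulla than in whole cortex (2492), 881 with a higher difference between tissue and thymocytes (1698), 764 higher in whole cortex than in its thymocytes (1288) and 1233 higher in whole medulla than in its thymocytes (2605). Genes with a lower difference numbered 183 within the arrays without a wide tail (299). Genes lower in subcapsular than in central cortex (60) numbered 91 with only the groups compared and 96 with array weights. Genes lower in perimedullary than in central cortex (5) numbered 3 with the smaller offset, 2 with the stricter filter and 10 with array weights. Genes lower in whole cortex than in its thymocytes (203) numbered 49 with a wide-tail term and 27 within the arrays without a wide tail. Genes lower in whole medulla than in its thymocytes (162) numbered 332 after quantile normalization. With the mean of the probe sets of a gene, 481 genes were higher in the subregions than in whole cortex (948). The correlation of the tissue comparison with the thymocyte comparison (0.574) was 0.544 with the smaller offset, 0.545 with no filter and 0.631 with the stricter filter, and that with perimedullary against subcapsular cortex (0.452) was 0.412 and 0.525 with the last 2 of these. The sign turned with plain-suffix probe sets for Ighm in thymocytes (0.349), Fscn1 in perimedullary against central (-0.143) and subcapsular cortex (-0.00865), and Ccne1 (-0.412), Mcm2 (-0.872) and Ptprc (1.11) in the subregions against whole cortex, where quantile normalization turned Rag1 (0.0664) and Ptprc (0.271).

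With each array left out in turn, genes higher in subcapsular than in central cortex numbered 75 (without central replicate 2) to 124, and genes lower in perimedullary than in central cortex 1 (without central replicate 1) to 5, with 2 without central replicate 3, 3 without perimedullary replicate 1 and 2 without perimedullary replicate 3. The named genes gave 5205 results with the same call under this, 78 weaker, 11 stronger and 0 reversed. Over the 8 settings in which the 261 list tests were rerun, 60 calls were lost, 45 gained and 0 reversed. Lost and gained were 16 and 10 with plain-suffix probe sets, 13 and 3 with the stricter filter, 11 and 5 with the mean of the probe sets, 9 and 2 after quantile normalization, 4 and 0 with the smaller offset, 2 and 7 with only the groups compared, and 0 and 9 with no filter. Medullary epithelial genes in perimedullary against subcapsular cortex gained their call with no filter (mean log2 fold change 0.421), the mean of the probe sets (0.48), plain-suffix probe sets (0.511) and only the groups compared (0.421). The lists were not rerun with array weights, with arrays left out or with the wide-tail alternatives. Dim genes depend on the offset, as signal near the background is limited by it. Replicate numbers do not pair the arrays by the labels. A replicate block gave 428 genes lower in whole cortex than in its thymocytes and 252 lower in whole medulla than in its thymocytes, lost 5 list calls and gained 9, among these the Notch (0.25) and cortical epithelial (0.219) lists in subcapsular against central cortex. Of 7 pairs of whole cortex and whole medulla with a shared number, 4 correlated over 0.1 (-0.033 to 0.26) and 3 matched their own number best. All 3 pairs of subcapsular and central cortex matched their own number best, at correlations of 0.0074 to 0.013, and no set of pairs lay over 0.1 throughout.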

Other observations

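The cholesterol genes were looked at as a pathway after Idi1, Sqle and Tmem97 were seen to fall, and 2 tests of it were chosen before its own values were seen, whereas the test of its rate per cell cycle change was chosen after. Further lists differed between perimedullary and subcapsular cortex. Immediate early genes rose in 6 of 19 cases (median log2 fold change 0.396, camera adjusted p = 2.5e-06), the TNF and NF-kB list in 5 of 15 (0.543, camera adjusted p = 0.00015), regulatory T cell genes in 4 of 9 (0.972, camera adjusted p = 0.002, lost with plain-suffix probe sets, mean 0.743), interferon-response genes in 5 of 17 (0.64, camera adjusted p = 8.4e-07), NKT and innate-like T cell genes in 5 of 12 (0.874, camera adjusted p = 0.00042) and MHC class II genes in 2 of 11 (0.815, camera adjusted p = 7.2e-07). B cell genes rose in 3 of 10 cases, or 4 adjusted over the list alone (0.782, camera adjusted p = 6.8e-06).

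Whole cortex exceeded its thymocytes also in dendritic cell genes (6 of 12 rose, camera adjusted p = 0.00022), basement membrane and adhesion genes (10 of 18, camera adjusted p = 3.9e-07), proteases (7 of 18, camera adjusted p = 1.2e-05) and Wnt genes (6 of 16, camera adjusted p = 0.0027). Whole medulla exceeded its thymocytes in cortical epithelial genes (11 of 14, camera adjusted p = 8.5e-12), MHC class II genes (11 of 11, camera adjusted p = 6.4e-11) and proteases (10 of 18, camera adjusted p = 9.5e-05).

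Genes of cholesterol synthesis may be higher together in subcapsular cortex. Idi1 (log2 fold change -2.12, SE 0.2), Sqle (-1.93, SE 0.18) and Tmem97 (-1.85, SE 0.29) fell in perimedullary against subcapsular cortex and prompted the test. Of 15 other genes of the pathway 14 lay below 0 and 6 fell, Hmgcs1 (-1.03), Fdft1 (-1.05), Lss (-1.03), Cyp51 (-1.3), Msmo1 (-1.4) and Insig1 (-1.17), with a median of -0.86 (camera adjusted p = 1.3e-07 over the 9 comparisons, and 0.0068 with an estimated correlation). In subcapsular against central cortex, which shares the 3 subcapsular arrays, the median was 0.6 (camera adjusted p = 4.2e-07, and 0.0068 with an estimated correlation). In perimedullary against central cortex none of the 15 was called and the median was -0.21 (camera adjusted p = 0.015, and 0.22 with an estimated correlation).

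That the cholesterol genes follow the share of cycling thymocytes cannot be told apart from other sources by the planned test, since in medullary against cortical thymocytes they were lower at the preset correlation (median -0.25, camera adjusted p = 0.045), which this explanation asks for, but not with an estimated correlation (camera adjusted p = 0.29). In whole medulla against whole cortex the median was -0.2 (camera adjusted p = 0.11). The change per change of the cell cycle list was 0.14 (interval 0.0189 to 0.515) of that in perimedullary against subcapsular cortex for the thymocytes and 0.109 (-0.0294 to 0.284) for the whole tissues. Both intervals lie below 1, the value for 1 rate in cortex and medulla. The rule for excluding 1 rate was first set on the thymocytes alone, and their interval went past its bound. It was widened to the whole tissues after both intervals were seen, so these values exclude 1 rate by no rule set beforehand. A link to division within the cortex alone stays open, as medullary thymocytes differ from cortical ones in more than division and the subregion comparisons share their arrays.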
